A study of Drosophila melanogaster with 12 samples.

How the data were processed

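RNA of Drosophila melanogaster Dmel-2 cells, a derivative of the Schneider line of embryonic, hemocyte-like cells grown in serum-free medium, was measured after LacZ RNAi (the control) or Dcr2 RNAi. Each RNA sample was split by size. RNA above 200 nt (large RNA) was depleted of ribosomal RNA and made into strand-marking libraries from 35 ng. RNA below 200 nt (small RNA) was depleted of 2S ribosomal RNA and made into small RNA libraries from about 475 ng. The 12 libraries form 4 groups of 3. The triplicates are technical, so every p-value measures only the spread between libraries of a single RNA sample per treatment, and treatment and RNA sample cannot be told apart.

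Per the submitters' processing notes, reads were trimmed with cutadapt and placed on the dm3 genome. The cutadapt version, the aligner and the counter are not given in the sources used here. The deposited files hold, per the file headers, the number of reads used for normalization and, for each transcript, exon and intron, whole-number read counts for reads placed at 1 site and for reads placed at several sites. Beside the counts stand RPKM values (reads per kilobase of feature, scaled to the number of normalization reads) that the authors computed from the unique reads and, as an upper value, with the multiply placed reads added. The large RNA files give both strands separately. The small RNA files combine strands and give no read lengths. In the large RNA files the columns named antisense held 98.9 to 99.5% of the unique reads on genes that no other gene overlaps, for genes of either genomic strand, and these columns were therefore treated as the gene's own strand. The large RNA files list 43329 transcripts of 16973 genes or named loci and 62261 distinct introns. The small RNA files list 43331, 16975 and 62262. Coordinates are those of the files (dm3).

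Each gene was represented by its transcript with the highest mean RPKM over the libraries of a fraction. The unit tested was log2 of (unique reads + 0.5) scaled to the authors' normalization reads as in RPKM but without division by length (RPM). Features with a group mean RPKM of at least 1 were tested. The test was limma 3.58.1 (lmFit, then eBayes with trend and robust fitting) in R 4.3.3, two-sided, with Benjamini-Hochberg (BH) adjustment over the features tested and a threshold of 0.05. In the text, rose and fell mean an adjusted p under that threshold, and log2 values are Dcr2 minus LacZ with the standard error (SE) of the fit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures. Means are given with the standard deviation (SD) over 3 libraries.

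The groups, comparisons, gene lists, filter, threshold and naming rule were fixed before the data were examined. The planned test was limma on log2(RPKM + 0.5) for RPKM, or a quasi-likelihood count model for counts. The test used departs from both plans. It was chosen after the files were seen, from simulations that also showed the real number of calls, and the count model was not run. Counts were simulated with changes in 200 features and a single extra spread for all features, estimated from the LacZ libraries. For large RNA genes that spread was the lowest value allowed, 1e-04. The spread of the Dcr2 libraries was not simulated. Between pairs of large RNA libraries chi-square per degree of freedom was 1.77 to 3.72 within Dcr2 and 1.44 to 1.65 within LacZ. The rates that follow may therefore be better than those in the data. In large RNA genes limma on log2(RPKM + 0.5) recovered 92.9% of the 2-fold changes, with 4.04% of 198 calls wrong. The test used recovered 97.0%, with 4.41% of 204 calls wrong. In small RNA genes it recovered 3.9% of the 2-fold and 11% of the 4-fold changes, and 0 of 12 calls were wrong. Limma on log2(RPKM + 0.5) recovered 4.88% of the 4-fold changes with 5 of 10 calls wrong, and limma with voom weights recovered more, 13.4%, with 9 of 23 calls wrong.

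Gene lists were compared with the other tested genes by camera (limma, preset correlation 0.01, lists of at least 3 tested members, BH over the lists of a fraction). The 20 lists were the siRNA, miRNA and piRNA pathways, antimicrobial and Toll/Imd genes, JAK-STAT and antiviral genes, heat shock and chaperone genes, histones, cytoplasmic ribosomal proteins, snoRNA host genes, small nucleolar and nuclear RNAs, microRNAs, hairpin siRNA loci, reported siRNA targets and overlap loci, cell cycle and DNA replication, dosage compensation, and markers of hemocytes, neurons, muscle, fat body and germline. Camera was repeated with a correlation estimated from the data, and fry (limma) was run beside it. With an estimated correlation no large RNA list kept its call. By fry, 14 of the 16 large RNA lists were called, 11 of them down, and 2 of the 14 small RNA lists. Genes whose exons overlap exons of a gene on the other strand by at least 50 nt (1948 pairs, 3612 genes) were compared with the other genes by camera. Genes changed in both fractions were compared by Fisher's exact test, two-sided.

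Genes named by rule were Dcr-2, the 6 largest rises and falls of each gene-level comparison (3 for introns and overlapping pairs) with a higher group mean of at least 5 and no overlap between the groups, and up to 2 members of each list. Further list members, and features of the opposite-strand and multiply placed comparisons, were named after their values were seen. Those 2 comparisons were added after the files were seen. The opposite-strand comparison took features with at least 10 reads, and the multiply placed comparison took features with at least 20 placements, as a mean over the 6 libraries of a fraction.

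A fold against a group with 0 reads is a lower bound, computed against 3 reads over the group. With 1 to 3 reads in a group, the ratio of pooled RPM is given with its exact (Clopper-Pearson) 95% interval. Such bounds and intervals cover counting error only, since the reads are PCR copies without molecular identifiers. Alternatives tried were pseudocounts of 0.1 and 1, no filter, a mean of at least 5, a 2-fold minimum, other scalings, multiply placed reads added, the longest transcript, a replicate block, each library left out in turn, other fits, and a smooth trend on transcript length removed. Scaling to the median gene sets each library's median log2 ratio to the mean library to 0, which for features with few reads does not set the median change between groups to 0. Transposable elements are not among the features of the files and were not analysed here.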

Results

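RNA was measured in 12 libraries of Drosophila melanogaster Dmel-2 cells treated with LacZ RNAi (control) or Dcr2 RNAi, with 3 large RNA and 3 small RNA libraries per treatment. Dcr-2 is the Dicer enzyme that cuts double-stranded RNA into small interfering RNAs (siRNAs). By its title, the series concerns antisense transcription of retrotransposons as a source of siRNA precursors. The large RNA libraries held 29576833, 35019939 and 25675521 normalization reads after LacZ RNAi and 22274983, 23369716 and 23758274 after Dcr2 RNAi. The small RNA libraries were about a hundredth of that size, with 338481, 285799 and 283271 reads after LacZ RNAi and 196054, 272187 and 206797 after Dcr2 RNAi. Unique reads on genes made up 51.8 to 52.4% of the large RNA reads after LacZ RNAi and 46.1 to 46.5% after Dcr2 RNAi. In small RNA they made up 62.3 to 65.2% and 75.6 to 76.7%.

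The knockdown target itself fell in large RNA and its small RNA reads rose. Dcr-2 (2R, 13462484 to 13469053) fell from 28.3 ± 0.42 to 9.46 ± 0.19 RPKM (SD, n = 3), a log2 change of -1.58 (SE 0.03, limma adjusted p = 8.81e-41). Away from exon 5 the fall was 4.75-fold, from 146.4 ± 2.43 to 30.8 ± 1.95 RPM (SD, n = 3). Exon 5 (13466921 to 13467617, 697 nt) held 24.7 ± 0.36 RPM after LacZ RNAi and 24.7 ± 0.926 after Dcr2 RNAi. On the strand opposite to the gene, exon 5 went from 0.313 ± 0.0764 to 13.7 ± 1.09 RPM. Small RNA reads on Dcr-2 rose from 24 to 11869 (log2 change 9.33, SE 0.142), and exon 5 held 22 and 11868 of them. Without exon 5, Dcr-2 had 2 small RNA reads after LacZ RNAi and 1 after Dcr2 RNAi (log2 change -0.09, limma adjusted p = 0.941).

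**Figure D1:**
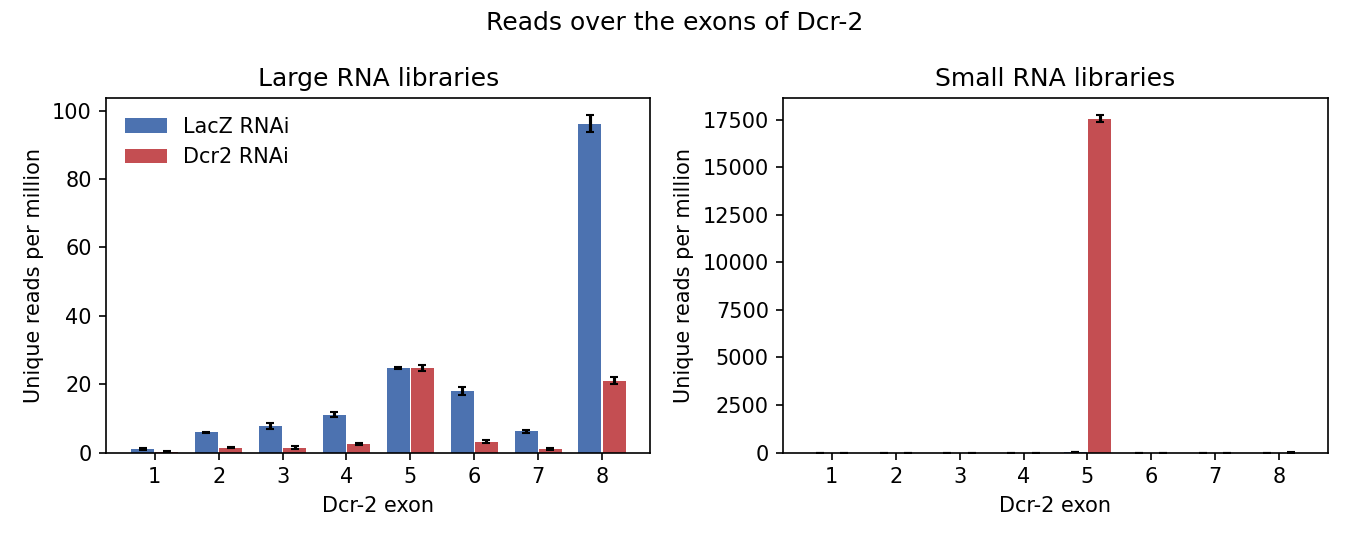
Unique reads (RPM) on each exon of Dcr-2 after LacZ RNAi (blue) and Dcr2 RNAi (red), in large RNA on the gene's own strand (left) and in small RNA (right); bars are means and error bars SD (n = 3). Exon 5 has 24.7 RPM in large RNA after either treatment and 17560 in small RNA after Dcr2 RNAi.

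What Dcr2 RNAi does to longer RNAs was asked over 7917 genes in large RNA. Among genes with a mean of at least 5 RPKM in the higher group and no overlap between the groups, the largest rises included CG5847 (3L, 20410218 to 20417429), from 1.9 ± 0.0583 to 5.83 ± 0.145 RPKM, and CG10801, from 5.58 to 15.5 RPKM. Zasp52, a PDZ and LIM domain protein of muscle Z-discs and cell adhesions, rose from 4.26 ± 0.328 to 11.1 ± 0.751 RPKM (SD, n = 3). The log2 changes were 1.62 for CG5847, 1.56 for a small non-messenger RNA at 2L, 5193471 to 5193516, 1.42 for the C-type lectin lectin-22C, 1.40 for CG33967 and 1.38 for Zasp52. Under the same criteria, the largest falls besides Dcr-2 included the antimicrobial peptide genes Dpt (diptericin), from 114.5 to 65.8 RPKM (log2 change -0.80, SE 0.039), and Def (defensin, -0.76, SE 0.139). The others were small nucleolar RNAs (snoRNAs), which guide RNA modification: snoRNA:Me18S-G1952 (-1.75, SE 0.446), snoRNA:Me28S-G980 (-0.81) and snoRNA:Me28S-A982b (-0.80). The last pair lost their calls when libraries were scaled to the median gene (limma adjusted p = 0.103 and 0.126). Without LacZ replicate 1, LacZ replicate 2 or Dcr2 replicate 2 the adjusted p of snoRNA:Me28S-A982b was 0.0533, 0.0711 and 0.0856, and that of snoRNA:Me28S-G980 was 0.0714 without LacZ replicate 3.

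Counted over all genes, limma called 680 rises and 5258 falls, of which 48 rises and 4 falls were at least 2-fold. The median log2 change was -0.23. With libraries scaled to the median gene it was -0.01, and the calls were 1664 rises and 1285 falls, so that rises made up 56.4% of calls in place of 11.5%. Of the original calls, 679 rises and 1285 falls were among these. That scaling moves all log2 changes up alike, and falls smaller than the shift change sign. Counts by either scaling are therefore given for most gene groups. Change also went with transcript length. Genes with transcripts of 1000 to 2000 nt had a median log2 change of -0.27, those of 4000 to 8000 nt -0.05, and the 80 genes of at least 8000 nt 0.40, and 73 of these 80 rose. The 48 genes that rose at least 2-fold had a median transcript length of 448.5 nt, against 1705 nt over all tested genes, and 18 of them, mostly tRNAs and snoRNAs, were under 200 nt, the size boundary of the large RNA fraction.

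**Figure D2:**
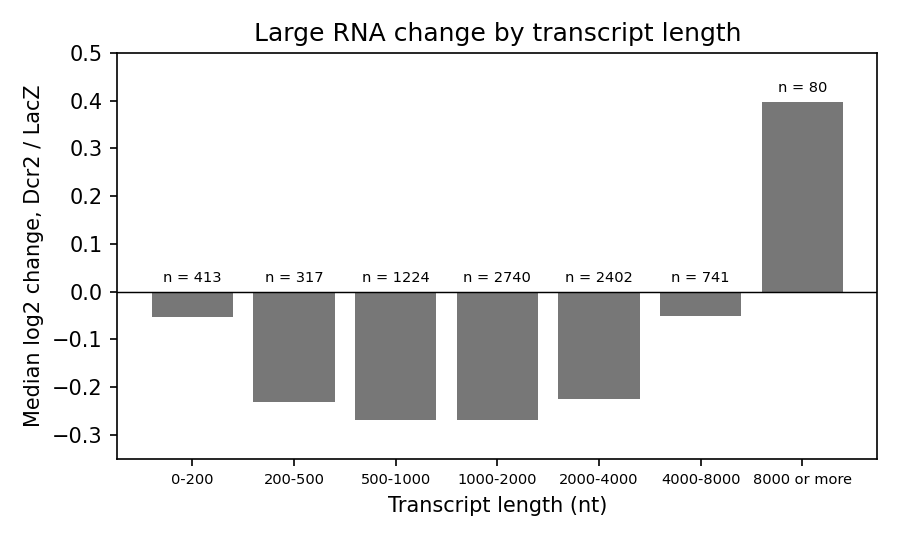
Median log2 change (Dcr2 over LacZ, authors' normalization) of the genes tested in large RNA, by length of their transcript in nt; bars are medians over the number of genes printed at each. The median goes from -0.27 at 1000 to 2000 nt to 0.40 at 8000 nt and more.

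In each small RNA pathway falls outnumbered rises with the authors' normalization, as over all genes, while after median scaling rises outnumbered falls in the miRNA pathway and equalled them in the piRNA pathway. In the siRNA pathway, 1 of 15 genes rose, 11 fell and 3 did not pass, with 3 rises and 7 falls after median scaling and 1 rise and 11 falls adjusted over the list alone. Beside Dcr-2, translin (trsn), a subunit of the C3PO nuclease, fell by 0.58 on the log2 scale. The helicase gene Rm62 rose by 0.09. AGO2, the Argonaute of siRNAs, had a log2 change of -0.22, and 0.00 after median scaling. The double-stranded RNA binding partner r2d2 had -0.10 (limma adjusted p = 0.105). The list was not called by camera (Down, adjusted p = 0.0574, and 0.311 with an estimated correlation), though its adjusted p was 0.0391 without LacZ replicate 1 and 0.0465 without Dcr2 replicate 3. This list includes Dcr-2, the knockdown target, and no camera result without Dcr-2 is given. In the miRNA pathway 3 genes rose and 4 fell of 10, also adjusted over the list alone, against 7 and 1 after median scaling. Not1, the scaffold of the CCR4-NOT deadenylase, rose by 0.64, and loqs, a partner of both Dicers, had -0.42 (limma adjusted p = 4.81e-06, and 0.079 with the length trend removed). Dcr-1, the Dicer of microRNAs, had 0.06 (limma adjusted p = 0.0797). Camera placed this list above other genes although its median was -0.09 (adjusted p = 0.0295, and adjusted p = 0.311 with an estimated correlation). In the piRNA pathway 1 gene rose and 10 fell of 18, against 3 and 3 after median scaling, among them del (-0.38) and the helicase gene Hel25E (-0.33). Camera did not call it (adjusted p = 0.691, and 0.773 with an estimated correlation).

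Most immune and stress genes changed in large RNA with the authors' normalization, as did most of all genes tested (5938 of 7917). Of 28 antimicrobial and Toll/Imd genes, 2 rose and 20 fell, and after median scaling 5 rose and 14 fell. The peptide genes Dpt, DptB (-0.48), Dro (-0.47), Mtk (-0.46) and CecA1 (-0.40) fell, as did the peptidoglycan-binding PGRP-SB1 (-0.64). The Imd pathway receptor gene PGRP-LC (0.30) and the receptor gene Tl (0.15) rose. Camera gave Down with adjusted p = 0.0268, and adjusted p = 0.374 with an estimated correlation. In the JAK-STAT and antiviral list 4 of 8 genes rose and 3 fell, against 5 and 1 after median scaling. TotA (0.66) and TotM (0.61), which encode secreted stress peptides, rose, as did the receptor gene dome (0.30), whereas vir-1 (-0.34) fell, as did the transcription factor gene Stat92E (-0.20, with 0.02 and limma adjusted p = 0.524 after median scaling). Camera gave Up with adjusted p = 0.00396, and adjusted p = 0.224 with an estimated correlation. Of 12 heat shock and chaperone genes, 0 rose by limma and 11 fell, all 11 of them the genes with an unadjusted p under 0.05, and 5 fell after median scaling. Hsp70Bb, whose paralogs share its sequence, fell by 0.63, and Hsp26 fell by 0.52. Camera gave Down with adjusted p = 0.0268, and adjusted p = 0.297 with an estimated correlation.

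Ribosomal protein, histone and replication genes mostly fell with the authors' normalization, and fewer of them after median scaling. Of 82 cytoplasmic ribosomal protein genes 3 rose and 75 fell, with 12 and 48 after median scaling, and with 3 and 76 adjusted over the list alone. RpL39 fell by 0.50, whereas RpL23A (3L, 1667192 to 1668620) rose by 0.94. Camera gave Down with adjusted p = 3.96e-10, and adjusted p = 0.244 with an estimated correlation. Of 12 snoRNA host genes 1 rose and 9 fell (2 and 3 after median scaling). The riser was Uhg7 (1.02), which overlaps RpL23A on the same strand by 116 nt. Of its 1709 and 2654 exon reads after LacZ and Dcr2 RNAi, 1610 and 2560 lay in the exon that reaches into RpL23A, and its other exons, with 99 and 94 reads, had a log2 ratio of 0.28, so that its rise may be of reads shared with RpL23A, whose exons outside Uhg7 had 1.13 (exons compared after these values were seen). RpS5a fell by 0.34. Camera did not call the hosts (adjusted p = 0.691, and 0.759 with an estimated correlation). The 4 tested histone genes are replication-independent members such as His3_3B (-0.40) and His4r (-0.39), and all 4 fell under either scaling. Camera gave Down with adjusted p = 0.0171, and adjusted p = 0.311 with an estimated correlation. Of 25 cell cycle and DNA replication genes 0 rose and 22 fell by limma, and 22 had an unadjusted p under 0.05; after median scaling 4 rose and 8 fell. RnrS, the small subunit of ribonucleotide reductase, had a log2 change of -0.42 and the replicative helicase gene Mcm5 -0.37. Camera gave Down with adjusted p = 0.021, adjusted p = 0.311 with an estimated correlation, and 0.301 after median scaling, which ended the call. Of 6 dosage compensation genes 0 rose and 4 fell by limma, the same number as had an unadjusted p under 0.05. The noncoding RNA roX2 fell by 0.39, and msl-3 fell by 0.32 but had -0.10 after median scaling (limma adjusted p = 0.197). After that scaling 2 of the 6 rose and 1 fell, and camera did not call the list (adjusted p = 0.691, and 0.759 with an estimated correlation).

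Hemocyte genes moved both ways. Of 10 markers 6 rose and 4 fell, with 7 and 1 after median scaling. Pxn (peroxidasin, 0.88), Hml (hemolectin, 0.82), the zinc finger gene ush (0.66) and the collagen gene Cg25C (0.44) rose, whereas the phagocytosis receptor gene eater (-0.31) and the receptor tyrosine kinase gene Pvr (-0.24, with -0.02 and limma adjusted p = 0.373 after median scaling) fell. Camera gave Up with adjusted p = 1.4e-05, and adjusted p = 0.244 with an estimated correlation. Markers of other tissues were few. The neuron marker elav had a log2 change of 0.02 (limma adjusted p = 0.798), neither of the 2 muscle markers Mef2 and Mlc2 passed, the fat body list held only Cg25C, and of 2 germline markers ovo fell (-0.35, limma adjusted p = 0.00651) while fs(1)Yb did not pass (-0.09). After median scaling 1 gene rose and 0 fell in each of the neuron, muscle, fat body and germline lists, so that the fall of ovo was no longer called.

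Among short and structured RNAs in large RNA, 20 of 269 small nucleolar and nuclear RNAs rose and 58 fell, against 30 and 9 after median scaling and 12 and 45 adjusted over the list alone. snoRNA:Me28S-A2958 rose from 3 to 11 reads, a ratio of 4.77 (exact 95% interval 1.26 to 26.6). Its call was lost without LacZ replicate 2, Dcr2 replicate 2 or Dcr2 replicate 3 (limma adjusted p = 0.146, 0.0506 and 0.13). Camera placed the list above other genes although its median was -0.09 (adjusted p = 6.66e-06, and adjusted p = 0.438 with an estimated correlation), and the call was lost after median scaling (adjusted p = 0.0948). Of 18 microRNA genes 0 rose and 0 fell by limma, 0 with an unadjusted p under 0.05, at a median of -0.05. Camera gave Up with adjusted p = 0.00396, and adjusted p = 0.224 with an estimated correlation, and after median scaling Down with adjusted p = 0.921. Of 4 hairpin siRNA loci, whose transcripts fold into long double strands, 2 fell. CG32207 had a log2 change of -0.45 (limma adjusted p = 0.0393, and 0.404 after median scaling), and its call was lost without LacZ replicate 1, LacZ replicate 3, Dcr2 replicate 1 or Dcr2 replicate 2 (adjusted p = 0.117, 0.107, 0.212 and 0.11). CG18854 had -0.19, which became 0.04 after median scaling and 0.07 with the length trend removed. After median scaling 1 of these 4 rose, and adjusted over the list alone 1 fell. Of 6 reported siRNA targets and overlap loci 2 rose and 3 fell, with 3 and 1 after median scaling. The receptor gene tkv rose by 0.49 and ATPsyn-beta fell by 0.33. Camera called neither the hairpin list (Up, median -0.16, adjusted p = 0.731, and 0.773 with an estimated correlation) nor the targets (Up, median -0.14, adjusted p = 0.593, and 0.759 with an estimated correlation).

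Of 17082 annotated introns tested in large RNA, 1185 rose and 1523 fell. Exons of other transcripts or genes within an intron were not removed, so that intron reads need not come from unspliced or intron-derived RNA. Under the same criteria of level and separation, the largest rises were in 3 overlapping introns of the microtubule-associated gene Jupiter, of which the one at 3R, 7430006 to 7430307, had a log2 change of 2.02 (SE 0.258). The largest falls were in introns of CG4692 (-1.68), CG6084 (-1.64) and veg (-1.62), each with 7 to 13 reads after Dcr2 RNAi. On log2 RPKM these 3 falls lost their calls (limma adjusted p = 0.06 for CG4692, 0.115 for CG6084 and 0.0854 for veg). The intron of veg also lost its call without LacZ replicate 1, LacZ replicate 3 or Dcr2 replicate 3 (limma adjusted p = 0.0866, 0.0805 and 0.0905), as did that of CG4692 without LacZ replicate 3 (0.0679). After median scaling 1531 introns rose and 837 fell, and rises made up 64.7% of calls in place of 43.8%. Without LacZ replicate 3 the falls numbered 968.

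The small RNA comparison asked which loci lose small RNAs when Dcr-2 is depleted. At several genes the reads were gone. The transcription factor gene ab (2L, 11257610 to 11259642) fell from 107 reads over the LacZ libraries (75.8 ± 7.37 RPKM, SD, n = 3) to 0, at least 26.5-fold lower (limma adjusted p = 7.51e-21). The centrosome gene spd-2 fell from 105 reads to 0 (at least 26.0-fold), CG17944 from 94 (at least 23.3-fold), CG3837 from 93 (at least 23.1-fold), CG34288 from 81 (at least 20.1-fold) and CG14628 from 55 (at least 13.6-fold). The largest rises other than Dcr-2, chosen by the same criteria, were small in reads. CG2278 rose from 0 to 12 reads (at least 5.38-fold) and snoRNA:Psi28S-3327b from 0 to 8 (at least 3.59-fold). The reads of snoRNA:U27:54Ea went from 3 to 14, a ratio of 6.27 (exact 95% interval 1.75 to 34.0). The log2 changes of snoRNA:Me28S-U2134b and psnoRNA:CG10576-a were 2.47 and 2.11. These 4 small nucleolar RNA calls were each lost without at least 1 library. The adjusted p (limma) of snoRNA:Psi28S-3327b was 0.135, 0.0777 and 0.0885 without LacZ replicates 1, 2 and 3, and 0.225 and 0.165 without Dcr2 replicates 1 and 3. That of snoRNA:U27:54Ea was 0.198 and 0.0847 without LacZ replicates 1 and 2, and 0.0622 and 0.0534 without Dcr2 replicates 1 and 2. For snoRNA:Me28S-U2134b it was 0.184 and 0.0866 without LacZ replicates 2 and 3, and 0.0534 and 0.0719 without Dcr2 replicates 2 and 3. For psnoRNA:CG10576-a it was 0.0742 and 0.0526 without LacZ replicates 2 and 3, and 0.0888 and 0.0534 without Dcr2 replicates 1 and 2.

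Over all 4281 genes tested in small RNA, limma called 21 rises and 84 falls, and 524 genes had an unadjusted p under 0.05. After median scaling 36 rose and 50 fell, so that rises made up 41.9% of calls in place of 20%, and the median log2 change went from -0.09 to 0.20, so that this scaling did not centre these genes. With libraries scaled to their microRNA reads 11 rose and 166 fell, and limma without trend and robust options called 2 rises and 32 falls. A pseudocount of 0.1 left 12 rises and 41 falls, and the fit on log2 RPKM 9 and 37, with CG2278 among the calls lost (limma adjusted p = 0.0653). Without LacZ replicate 1, 2 or 3 the calls numbered 59, 61 and 58, with 45, 48 and 41 falls; rises numbered 13 without LacZ replicate 2 and 12 without Dcr2 replicate 2. On simulated counts of this depth the test recovered 11% of 4-fold changes, so that changes at genes with few reads were mostly not detectable.

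**Figure D3:**
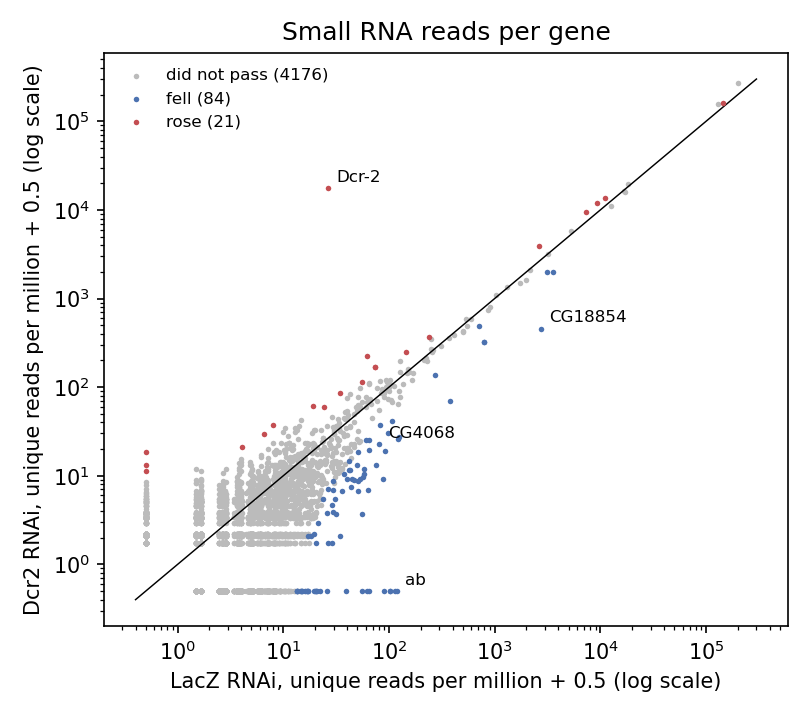
Unique small RNA reads (RPM plus 0.5) of the genes tested, LacZ RNAi against Dcr2 RNAi (log scales, means of 3 libraries per group), with falls in blue, rises in red and the line of equal values. Dcr-2 lies far above the line, and 84 of the 105 genes called lie below it, against 50 falls after median scaling.

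Hairpin siRNA loci lost small RNA reads. Of 4 tested, 2 fell and 2 did not pass, also after median scaling and adjusted over the list alone. CG18854 fell from 1511 ± 129 to 253.1 ± 36.8 RPKM (SD, n = 3), a log2 change of -2.58 (SE 0.124, limma adjusted p = 7.22e-91), and CG4068 from 26.6 to 7.32 RPKM (log2 change -1.72, SE 0.368, adjusted p = 0.000313). Fitted by limma without trend and robust options, both calls were lost (adjusted p = 0.054 for CG18854 and 0.227 for CG4068), and that of CG4068 was also lost on log2 RPKM (0.205). The median of the list was -0.90, and camera gave Down with adjusted p = 2.86e-08, and adjusted p = 0.0275 with an estimated correlation. Of 57 microRNAs 5 rose and 2 fell, with 9 and 1 after median scaling and 6 and 5 adjusted over the list alone. mir-275 had a log2 change of -0.84 and mir-14 -0.67, the call of mir-14 being lost after median scaling (limma adjusted p = 0.183). Without trend and robust options both calls were lost (limma adjusted p = 0.499 for mir-275 and 0.617 for mir-14). The rises, in mir-283 (0.59), mir-305 (0.39), mir-7 (0.37), mir-9c (0.32) and mir-276a (0.14), were smaller. Scaling to microRNA reads lowers all these rises alike, as it moved the median log2 change over small RNA genes from -0.09 to -0.36. Camera gave Up although the median was -0.02 (adjusted p = 0.0045, and adjusted p = 0.261 with an estimated correlation), and not without Dcr2 replicate 1, 2 or 3 (adjusted p = 0.126, 0.0907 and 0.105). Of 206 small nucleolar and nuclear RNAs 10 rose and 4 fell, with 17 and 2 after median scaling and 16 and 7 adjusted over the list alone. snoRNA:Psi18S-176 fell from 17 reads to 0 (at least 4.21-fold), a call lost without LacZ replicate 3 (limma adjusted p = 0.0758). Camera gave Up with adjusted p = 0.00319, and adjusted p = 0.261 with an estimated correlation.

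Few members of the messenger RNA lists passed the test in small RNA, where it recovered 11% of simulated 4-fold changes. In the siRNA pathway only Dcr-2, by its reads in exon 5, rose of 13 genes, and 2 had an unadjusted p under 0.05 by limma. Camera gave Up although the median was -0.09 (adjusted p = 3.57e-15, and 0.0134 with an estimated correlation). The list includes Dcr-2, the knockdown target (log2 change 9.33), which lifted the list mean to 0.625. No camera result without Dcr-2 is given, so that the call may rest on Dcr-2 alone. The call was lost after median scaling (adjusted p = 0.0682) and without Dcr2 replicate 2 (0.242). In the miRNA pathway 1 of 7 genes fell. AGO1, the Argonaute of microRNAs, went from 15 reads to 1, a ratio of 11.2 (exact 95% interval 1.72 to 470), with limma adjusted p = 0.0484, and with 0.147 after median scaling. Without LacZ replicate 1, 2 or 3 or Dcr2 replicate 1 or 2 its adjusted p was 0.224, 0.228, 0.224, 0.0558 and 0.0932. With the replicate number as a block it was 0.0703. Camera did not call that list (adjusted p = 0.648, and 0.719 with an estimated correlation). Of 80 ribosomal protein genes 0 changed by limma, with 7 at an unadjusted p under 0.05. Their median was 0.19, and camera gave Up with adjusted p = 0.028, adjusted p = 0.261 with an estimated correlation, and 0.0596 without LacZ replicate 3. By limma 0 genes changed in the other lists. At an unadjusted p under 0.05 these had 2 of 10 piRNA pathway genes, 2 of 21 antimicrobial and Toll/Imd genes, 0 of 2 JAK-STAT genes, 1 of 7 heat shock genes, 1 of 4 histone genes, 0 of 10 snoRNA hosts, 0 of 4 reported targets, 0 of 14 cell cycle genes, 0 of 1 dosage compensation gene, 2 of 7 hemocyte markers, and 0 of the 1 fat body and 1 germline marker. Adjusted over the list alone, 1 histone gene and 1 hemocyte marker fell. The adjusted p of camera was 0.511 for the piRNA pathway, 0.358 for antimicrobial, 0.113 for heat shock, 0.511 for histone, 0.235 for snoRNA host, 0.576 for target, 0.648 for cell cycle and 0.838 for hemocyte genes. Heat shock genes, with a median log2 change of 0.97 (0.84 with a gene without reads in a group at its bound), had 0.032 without Dcr2 replicate 3 and 0.0472 after median scaling, both Up. No neuron or muscle marker was tested.

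Small RNA reads in introns also fell more often than they rose, with 19 rises and 72 falls among 2560 introns. Introns of CG14290 (49 reads to 0, at least 12.1-fold), CG34357 (45 to 0, at least 11.2-fold) and srp, which encodes a GATA factor of hemocytes (38 to 0, at least 9.42-fold), had the largest falls among introns under the same criteria. The largest rises so chosen were in introns that hold small nucleolar RNAs: that of RpS4 went from 0 to 8 reads (at least 3.59-fold), that of Uhg1 from 3 to 14, a ratio of 6.27 (exact 95% interval 1.75 to 34.0), and that of CG10576 had a log2 change of 2.11. The call of RpS4 was lost without Dcr2 replicate 1 or 3 (limma adjusted p = 0.244 and 0.132). After median scaling 17 introns rose and 245 fell, rises making up 6.49% of calls in place of 20.9%. That scaling did not centre these introns, whose median log2 change went from -0.09 to -0.53. On log2 RPKM 3 rose and 7 fell, and the calls of RpS4, Uhg1, CG10576, CG34357 and srp were lost. Without LacZ replicates 1 and 3 the calls numbered 58 and 60, and the falls were 43, 47 and 38 without LacZ replicates 1, 2 and 3. Without Dcr2 replicate 2 there were 264 calls, 185 of them rises.

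Genes that overlap on opposite strands can form double-stranded RNA, and they were compared with the other genes. In small RNA, where strands are combined, a read within an overlap can count for both genes. In small RNA, ab, regucalcin and sec15 were the largest falls in such pairs under the same criteria. Regucalcin, a calcium-binding protein gene, went from 31 reads to 1, a ratio of 23.1 (exact 95% interval 3.84 to 940), and the exocyst gene sec15 from 28 to 2, a ratio of 10.4 (2.63 to 90.2), a call lost without LacZ replicate 3 (limma adjusted p = 0.0547). On log2 RPKM the calls of regucalcin and sec15 were lost (limma adjusted p = 0.0653 and 0.169). The largest rise so chosen (1.22) was in CG7974 and snoRNA:Me28S-A2634c, which overlap on opposite strands. Both held the same number of reads in every library (66 and 115 over the LacZ and Dcr2 groups). These may be the same reads, so that a rise of CG7974 itself is not shown. The next rise was nc_5362 (0.64), and these calls were lost without trend and robust options (limma adjusted p = 0.403 and 0.657). Of these nc_5362 was also not called without LacZ replicate 1 or 2 or Dcr2 replicate 2 or 3 (limma adjusted p = 0.149, 0.0846, 0.072 and 0.165). Nor was nc_5362 called with the replicate number as a block or scaled to microRNA reads (limma adjusted p = 0.0686 and 0.328). Falls made up 1.98% of 1513 overlapping genes and 1.95% of 2768 others, and camera gave Down with p = 0.0101, and p = 0.146 with an estimated correlation. For overlaps of at least 200 nt the shares were 2.98 and 1.8% (camera p = 0.0013, and 0.1 with an estimated correlation). For any overlap they were 1.85 and 2.05% (camera p = 0.0378, and 0.213 with an estimated correlation). In large RNA, CG42611 (89.1 to 186.6 RPKM, log2 change 1.07), Uhg7 and CG2025 (0.98) had the largest rises of overlapping genes under these criteria, and CG34242 (-0.71) and CG10102 (-0.65) fell. Falls made up 73.8% of 2469 overlapping genes and 63.1% of 5448 others. Camera gave Down with p = 0.0492, but p = 0.419 with an estimated correlation, 0.785 for overlaps of at least 200 nt and 0.0971 after median scaling. It gave 0.0576, 0.0565 and 0.0833 without LacZ replicate 3, Dcr2 replicate 2 and Dcr2 replicate 3.

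Whether genes that lost small RNA reads gained large RNA was asked over the 3769 genes tested in both fractions. Of these, 66 fell in small RNA, 294 rose in large RNA and 8 did both, where 5.15 would be drawn by chance. The odds ratio was 1.65 (95% interval 0.673 to 3.51, Fisher's exact test, two-sided, p = 0.169). After median scaling 13 genes did both where 7.43 would be drawn by chance (odds ratio 2.17, 1.01 to 4.47, Fisher's exact p = 0.036), and with a 2-fold minimum 0 genes did both where 0.323 would be drawn by chance (p = 1.0), too few to show a direction. Among the 66 genes with fewer small RNA reads, the chromatin remodeling ATPase gene brm rose by 0.79 in large RNA. Its exons after the middle of the transcript had a log2 ratio of 0.82 and those before it -0.08, so that the rise lay in the later exons. As whole genes, pyd rose by 0.73 and headcase by 0.71, while 39 of the 66 fell in large RNA. After median scaling 24 of the 66 rose and 3 fell. Across genes, which are not independent replicates, Spearman's rho between both changes was -0.057.

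Large RNA on the strand opposite to genes was tested at 3252 genes, of which 272 rose and 368 fell. Dcr-2 rose from 0.464 ± 0.0231 to 14.0 ± 1.16 RPM (SD, n = 3), a log2 change of 4.86 (SE 0.151, limma adjusted p = 4.14e-22). CG42611 (1.78) also rose, but its opposite-strand reads were 0.12 and 0.21% of all its reads, less than the share left by the 98.9 to 99.5% that genes hold on their own strand, which itself rose by 1.07. CG6901 (1.59) rose with 1 own-strand read in either group, and CG13587 (-1.09), with 0 own-strand reads, fell, as did CG10320 (-0.92) and CG18476 (-0.92). Of the 640 calls, 395 were in genes that an annotated gene overlaps on the other strand, as were 2116 of the genes tested. After median scaling 343 rose and 177 fell, rises making up 66.0% of calls in place of 42.5%. Without LacZ replicates 1, 2 and 3 the calls numbered 421, 423 and 380, with 181 to 208 falls.

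Reads placed at several sites, which include copies of repeats inside introns, fell at introns in small RNA and rose there in large RNA. The same read counts at each of its sites, and a site counts in every intron that covers it, so that features are not independent. In large RNA only placements on the gene's own strand were counted, whereas small RNA combines strands. The fractions are therefore not measured alike. In small RNA, an intron of Snoo (2L, 7976686 to 7984130) went from 63900 ± 6000 to 25050 ± 1320 placements per library, scaled as RPM (SD, n = 3), and an intron of the cell junction gene pyd from 64190 ± 5470 to 20850 ± 802. An intron of kraken (2L, 853006 to 853191) went from 183.1 ± 48.6 to 0. Of 678 introns 43 rose and 567 fell (median log2 change -1.13), and placements at introns went from 3.26 ± 0.274 to 1.54 ± 0.0404 per read. At the hairpin locus CG4068 multiply placed small RNA fell from 3190 ± 340 to 320.5 ± 43.7 on that scale, a log2 change of -3.31 (limma adjusted p = 2.28e-96). Among genes in small RNA 124 rose and 246 fell of 530. There CG9866 fell from 279.6 ± 57.9 to 2.84 ± 2.52, and tRNA:P:35Bd, with its copies, rose from 30.2 to 168.9 on that scale (2.54). In large RNA, 536 of 1646 introns rose and 94 fell (median 0.45), and placements at introns went from 0.922 ± 0.0101 to 1.2 ± 0.04 per read. The adenylyl cyclase gene rut had an intron with 83290 ± 1020 and 108900 ± 4640 placements on that scale, and an intron of the RNA-binding gene pum had a log2 change of 2.99 (limma adjusted p = 0.00857). Among genes in large RNA 170 rose and 331 fell of 978. Scaled to unique gene reads, 22 large RNA introns fell in place of 94, and without LacZ replicate 2 there were 1034 calls, 945 of them rises.

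**Figure D4:**
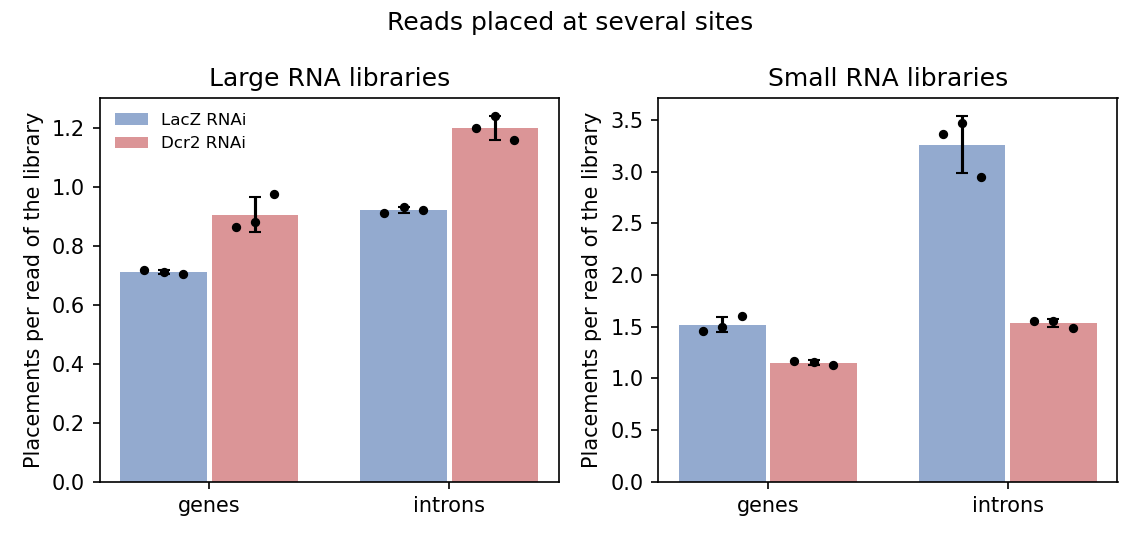
Placements of multiply placed reads per read of the library at genes and introns, in large RNA (left) and small RNA (right), after LacZ RNAi (blue) and Dcr2 RNAi (red); points are libraries and bars are means with SD (n = 3). At introns the mean goes from 3.26 to 1.54 in small RNA and from 0.922 to 1.2 in large RNA. Large RNA placements are those on the gene's own strand, and small RNA placements are of both strands.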

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

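Both results here lie outside the main comparisons, and the test of library totals given with the second was chosen after the shift it measures was seen.

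At exon 5 of Dcr-2, large RNA reads on the strand opposite to the gene reached 13.7 ± 1.09 RPM after Dcr2 RNAi (SD, n = 3), against 0.313 ± 0.0764 after LacZ RNAi. It drew attention because these reads are outside the own-strand comparison and above the level of the control libraries. The same exon held 11868 of the 11869 small RNA reads of Dcr-2 after Dcr2 RNAi, and without it the log2 change of Dcr-2 in small RNA was -0.09 in place of 9.33. A candidate explanation is that reads of both strands come from the double-stranded RNA used for the knockdown, but its sequence was not used here and the cause was not tested. After Dcr2 RNAi the opposite-strand reads numbered 284, 316 and 354 in exon 5, and 0 in each library in exons 4 and 6 and introns 4 and 5. This argues against opposite-strand transcription that runs past exon 5 on either side. Transcription of the opposite strand confined to exon 5 stays open.

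Reads of CR41609 (chromosome U, 4570872 to 4571822), a locus whose reads have several sites, made up 4.76 ± 0.169% of the large RNA reads after Dcr2 RNAi and 1.07 ± 0.00577% after LacZ RNAi (SD, n = 3). It drew attention because multiply placed reads are outside the main comparison and rose above the control libraries. CR40741 and CR40546 held near-equal shares of large RNA (4.75 and 4.71% after Dcr2 RNAi, 1.06% each after LacZ RNAi). A read counts at each of its sites, so that these shares may be of the same reads. In small RNA, which combines strands, CR41609 held 2.17% after LacZ RNAi and 1.89% after Dcr2 RNAi. The large RNA shares are of its own strand only. Such reads may lower every other gene after Dcr2 RNAi through the totals that the authors divided by. With the reads of CR41609 taken out of the totals, the median log2 change over large RNA genes was -0.18 (exact value -0.179) in place of -0.23, which argues against them as the whole cause of the excess of falls. Scaling to unique gene reads gave -0.07 (exact value -0.065), but it removes a common shift whatever its cause, so that other multiply placed reads and a lower share of gene RNA both stay open. Whether the reads of CR41609 differ between the treatments, between the RNA samples taken or between the preparation of those samples cannot be told apart with a single RNA sample per treatment.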

How the results depend on the processing

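The design sets a limit: each group is a single RNA sample measured in 3 libraries, so that no alternative separates treatment from RNA sample, and 3 against 3 libraries give only 10 splits. The test itself (limma on log2 RPM) was chosen after the data were seen. The planned count models (edgeR, and DESeq2 as its alternative) were not run, nor were the 9 of 65 alternatives laid out at the start that concern transposable elements, and 28 alternatives were added later, among them RPKM, voom weights, scaling to unique gene reads, totals without CR41609 reads, median scaling of the lists and overlapping genes, the length trend and all those for opposite-strand and multiply placed reads. Depth limits small RNA most. Except where a cause is named, the cause was not tested. Over all alternatives, named features kept direction and side of the threshold in 1476 of 1588 comparisons and lists in 240 of 270. Replicate numbers did not pair the libraries: correlations of the same number across groups were -0.168 to -0.072 over large RNA genes. With the replicate number as a block, large RNA genes had 672 rises and 5206 falls, and small RNA genes 19 and 74.

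Large RNA genes (5938 calls, 680 rises, 5258 falls) gave 2949 calls with median scaling (1664 and 1285), 3618 scaled to unique gene reads (1302 and 2316) and 2768 with the length trend removed (1418 and 1350). The first of these scalings shifts every gene alike by construction. A 2-fold minimum left 52 (48 and 4). CG18854 went from -0.19 to 0.04 (0.037) with median scaling and to 0.07 (0.073) with the length trend removed. Large RNA introns (2708, 1185, 1523) had 2137 rises with no filter, 1403 calls and 321 rises with a mean of at least 5 (fewer introns tested), 837 falls with median scaling, 307 calls (227 and 80) with a 2-fold minimum and 452 (221 and 231) on log2 RPKM. Leaving out each library in turn gave 968 to 1655 falls.

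Small RNA genes (105, 21, 84) gave 53 calls (12 and 41) with a pseudocount of 0.1, 32 rises with a mean of at least 5, 36 rises and 50 falls with median scaling, 1164 calls (144 and 1020) with multiply placed reads added, 46 (9 and 37) on log2 RPKM, 34 (2 and 32) without trend or robust fitting, 191 calls and 165 falls with voom weights, 177 calls (11 and 166) scaled to microRNA reads, and 5 rises without snoRNA, snRNA and microRNA genes (fewer genes tested). The RPKM fit shared 26 of the 105 calls and voom 103. Leaving out each library in turn gave 58 to 119 calls, 12 to 17 rises and 41 to 103 falls. Small RNA introns (91, 19, 72) gave 53 calls and 34 falls with a mean of at least 5, 262 calls and 245 falls with median scaling (which moved their median log2 change from -0.09 to -0.53), 1177 (71 and 1106) with multiply placed reads added, 10 (3 and 7) on log2 RPKM and 142 (29 and 113) with at least 10 reads. Leaving out each library gave 58 to 264 calls, 14 to 185 rises and 38 to 79 falls, the highest calls and rises without Dcr2 replicate 2.

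Opposite-strand calls (640, 272, 368) had 177 falls with median scaling and were 157 (133 and 24) with a 2-fold minimum. Leaving out each library gave 380 to 710 calls and 181 to 455 falls. Multiply placed reads in large RNA introns (630, 536, 94) had 22 falls scaled to unique gene reads and were 32 (32 rises and, by limma, 0 falls) with a 2-fold minimum, and leaving out each library gave 515 to 1034 calls and 441 to 945 rises. In small RNA introns 17 of 43 rises were at least 2-fold.

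Small RNA of Dcr-2 went from 9.33 (9.327) to -0.09 (-0.091) without exon 5, which by construction drops nearly all its reads. With an estimated correlation the lists called by camera went from 10 to 0 in large RNA, where 3 had an unadjusted p under 0.05, and from 5 to 2 in small RNA (3 to 5 with each library left out). The siRNA pathway list, which includes Dcr-2 itself, is among those 2. The hemocyte list in small RNA changed direction without Dcr2 replicate 2 (adjusted p = 0.778) and without Dcr2 replicate 3 (0.909), over a range of 0.778 to 0.935. With median scaling 7 large RNA lists and 5 small RNA lists were called, and in large RNA the direction changed for the piRNA pathway (adjusted p = 0.921), microRNAs (0.921) and dosage compensation (0.857). For overlapping genes in large RNA camera p went from 0.0492 to 0.785 at 200 nt, 0.419 with an estimated correlation and 0.0971 with median scaling (0.0411 to 0.0833 with each library left out), and in small RNA from 0.0101 to 0.146 with an estimated correlation. Fisher's exact p for genes changed in both fractions went from 0.169 to 0.036 with median scaling, and to 1.0 with a 2-fold minimum, where 0 genes were seen and 0.323 drawn by chance, too few to show a direction.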

Other observations

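In this part the tests of messenger RNA fragments, of median scaling, of the length trend by transcript length and of all splits of the libraries were chosen after the results were seen.

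Removing the length trend was bound to leave 40 of the 48 genes that rose at least 2-fold in large RNA about as high or higher. Tested genes of their lengths, under 4000 nt, had median log2 changes of -0.27 to -0.05. The values for these 40 thus show only that the trend at their lengths ran against a rise, and the test decides nothing further. With the trend removed, the median log2 change of the 22 with transcripts of 200 to 4000 nt was 1.499 (SD 0.242) in place of 1.24, with all 22 still called, and that of the 18 under 200 nt was 1.54 (exact value 1.538, SD 0.466) in place of 1.53, with 15 still called. Those 18, mostly tRNAs and snoRNAs, lie below the size boundary of the fraction, and a different carry-over of short RNAs was not tested. For the 8 of at least 4000 nt the median went from 1.28 (SD 0.195) to 0.85 (exact value 0.855, SD 0.46), no longer 2-fold, so that a length trend stays open for them as a set although all 8 were still called. The members differed: CG5847 (1.616 to 1.497) and CG33967 (1.402 to 1.38) changed little, CG5794 (1.323 to 1.085) and trol (1.359 to 0.976) more, and nej (1.101 to 0.734), mask (1.055 to 0.625), CG42611 (1.067 to 0.538) and dumpy (1.229 to 0.105) most. A loss reaching over much of 1 end of long RNAs is argued against for long transcripts in general. In 331 transcripts of at least 5000 nt, the exons before and after the middle of the transcript, summed on each side, changed alike (median difference -0.005, quartiles -0.102 and 0.097). A loss confined to the outermost exons would be diluted in such sums and stays open. Only 7 of the 48 genes were among these transcripts (-0.062, SD 0.299), and shorter ones were not tested. A difference between the RNA samples taken, apart from the treatment, stays open for all 48.

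Small RNA reads that fell at 84 genes may reflect siRNAs made from both strands, as a hypothesis. Median scaling moves all log2 changes up alike, and 50 of the 84 were still called with it. These 50, with a median of 49 reads over the LacZ libraries, went from a fitted median of -2.99 to -2.69. This argues against a shift of that size as the whole cause of their falls and covers no larger shift. The other 34, with a median of 25 reads over the LacZ libraries, lost their calls (limma adjusted p 0.0596 to 0.627). Their fitted median went from -2.18 (SD 0.685) to -1.89 (exact value -1.889, SD 0.685). Median scaling adds the same amount to every gene, so that this small move was fixed in advance and decides nothing for the 34. Scaling to microRNA reads moves changes down and so decides nothing. Fragments of messenger RNAs that themselves fell are argued against for the 66 falling genes tested in large RNA. Against a median small RNA change of -2.52, their median large RNA log2 change was -0.15 (SD 0.289, lowest -0.50) with the authors' normalization, by which 39 fell, and 0.07 (exact value 0.069) relative to the median gene, by which 3 fell. The other 18, among them ab, CG17944, CG3837 and CG14628, had no large RNA test, and this explanation stays open for them. For transcription of both strands, the 67 falling genes with at least 100 large RNA reads had a median opposite-strand share of 2.46% after LacZ RNAi. That was at percentile 100 of 10000 random sets matched on own-strand large RNA level, whose median was 0.457% and whose 95th percentile was 0.779%. The sets were not matched on small RNA reads. A high share may thus go with having many small RNA reads rather than with losing them. By annotated overlap on the other strand the shares were near-equal. Falls made up 1.98% of 1513 genes overlapping by at least 50 nt and 1.95% of 2768 others. These shares were 2.98 and 1.8% at 200 nt, and 1.85 and 2.05% for any overlap, so that annotated overlaps gave no steady excess of falls. Read lengths, which would tell siRNAs from other small RNAs, are not in the files used here.

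Other splits of the 6 libraries of a fraction into 3 and 3 are too few (10, the real one included) for a share under 0.05. The real split was in each case the 1 of 10 with the most calls. The real number and the highest of the other splits were 5938 and 0 for large RNA genes, 105 and 1 for small RNA genes, 2708 and 0 for large RNA introns, 91 and 0 for small RNA introns, 640 and 0 for the opposite strand, 630 and 0 for multiply placed reads in large RNA introns, and 610 and 2 for those in small RNA introns.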
